A study of Mus musculus with 6 samples.

How the data were processed

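RNA was measured by sequencing in the hippocampus of mice of 2 inbred strains, C57BL/6 and DBA/2, with 3 libraries per strain. Strain was taken from the strain label and the replicate number from the sample title. Per the labels' protocols, total RNA was extracted with TRIzol from frozen hippocampus chosen at random within a strain, libraries were made with an NEBNext Ultra RNA kit, and indexed libraries were run together on an Illumina HiSeq. The labels state neither sex, age nor substrain. They do not say plainly whether each library came from 1 animal, so p-values measure the spread between these libraries, which may be partly technical. Per the submitters' processing notes, Trimmomatic 0.30, HISAT2 2.0.1 and Cufflinks 2.2.1 were used with genome build GRCm38. The counting program, the gene annotation and whether counting used strand are not given in the sources used here.

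The authors deposited whole-number counts per gene, not normalized, for 51912 genes, of which 31719 had a count in at least 1 library. The authors also deposited FPKM values beside the counts. These FPKM values were checked against the counts, and each equalled the count per kilobase of the listed exonic length and scaled by the library's total count, within 0.005. No row lacked a gene name. The table also held 12 columns of per-sample values that match no labelled sample, and these were not used in any step. Of the gene IDs, 99.6% were found in GENCODE M21, whose build is also GRCm38, and gene coordinates come from it, counted from 1.

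Total counts were 16826010, 13867280 and 20185683 in the C57BL/6 libraries and 16912153, 16807559 and 13839366 in the DBA/2 libraries. A gene with 0 counts in a library is limited to 3 counts, or 0.149 to 0.217 CPM at these depths. Such floors and the intervals on ratios of counts cover counting error only. Libraries of 1 strain differed by more than sampling noise, with a chi-square per degree of freedom of 3.36 to 4.22 between pairs within a strain and 15.02 to 20.49 between strains, so none was treated as a repeat of another library. This does not show whether libraries of a strain came from separate animals.

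Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, TMM factors, filterByExpr by strain) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over 17517 genes. A gene was called at an adjusted p under 0.05. Log2 fold changes are DBA/2 over C57BL/6, so positive values are higher in DBA/2. Levels are CPM (counts scaled to a common library total, with TMM factors), as mean ± SD over the 3 libraries of a strain. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The script was tested on simulated counts for the DBA/2 against C57BL/6 comparison with 100 genes changed 1.5-fold and 100 changed 2-fold among 17263 tested. It recovered 73% of the former and 89% of the latter, and 8.47% of its 177 calls were false, above the nominal 5%.

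The 33 gene lists, the tests, the alternatives and the rule for named genes were written before the data were examined. Lists with at least 5 tested members, 31 in all, were tested as sets with camera of limma 3.58.1 at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over these lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation no list passed, and the lowest adjusted p was 0.897. The named genes are the 10 largest rises and the 10 largest falls among called genes whose libraries separate the strains and whose mean in the higher strain is at least 5 CPM, leaving out predicted genes, clone names and pseudogenes. To these come up to 3 called members of each list with the largest absolute change, or the 2 most abundant members of a list without a call, all measured members of the strain-variant and sex-linked lists, and the 5 genes of lowest adjusted p not yet among the largest changes. A few genes that this rule takes are not reported here. The others number 113, of which 102 were called, and the text prints the values of most of them.

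Genes with similar transcripts were grouped because the authors' counting could split their reads. The longest GENCODE M21 transcript of each gene with at least 10 counts was aligned to the others with megablast (BLAST 2.17.0). Genes that do not overlap and share at least 200 aligned bases at 95% identity, over at least 0.5 of the shorter transcript, were joined into 627 families of 1690 genes. A copy is a family member with 1 exon or annotated as a pseudogene, and the main copy of a gene is the one with the highest mean level over both strains.

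Alternatives were DESeq2 size factors, library size alone, no filter on low counts, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, an added threshold of 1 on the absolute log2 fold change, the replicate number as a block, leaving out each library in turn, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), and named symbols only. The FPKM fits kept genes of at least 1 FPKM in 3 libraries. Scaling and tests meant for a table without counts were not run. Counts summed over families, and a fit without the 2 C57BL/6 libraries that hold Xist counts, were added after seeing the data. Gene Ontology terms in the deposited table with 15 to 500 tested genes were tested with a one-sided hypergeometric test among tested genes with a term. Pairs of neighbouring called genes were compared with 10000 random orders of the genes, and windows of 10 Mb with at least 20 tested genes by a hypergeometric test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.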

Results

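Transcript levels were measured in the hippocampus of mice from 2 inbred strains that are widely used as parents of genetic crosses, C57BL/6 and DBA/2. Each strain had 3 libraries, with total counts from 13867280 to 20185683 in C57BL/6 and from 13839366 to 16912153 in DBA/2. The first principal component of log2 CPM held 70.5% of the variance and separated the strains. The question stated for the series was which genes differ in level between the strains.

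Some genes of antigen presentation (10 of 22 tested), microglia (9 of 20), myelin (8 of 20) and the early response to neuronal activity (12 of 22) were lower in DBA/2. These lists passed as sets with a preset correlation in camera and not with an estimated one (adjusted p = 0.897 with an estimated correlation for each). Markers of neighbouring thalamus and habenula, with a median log2 fold change of -1.34, fell beside the myelin genes. H2-K1, a classical MHC class I gene, fell from 21.2 ± 1.21 CPM in C57BL/6 to 0.715 ± 0.0729 CPM in DBA/2 (SD, n = 3 each). Poorer mapping of DBA/2 reads to this gene could add to that fall and was not tested. Fos, an immediate early transcription factor, fell from 33.9 ± 0.952 to 15.1 ± 2.64 CPM, and Fcrls, a microglial surface receptor, from 19.8 ± 1.72 to 3.64 ± 0.731 CPM (SD, n = 3 each). Stab2, a scavenger receptor for hyaluronan, rose from 2.19 ± 0.593 to 85.6 ± 19.4 CPM (SD, n = 3 each). Of 17517 genes tested, 4000 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1593 higher and 2407 lower in DBA/2. The median absolute log2 fold change of called genes was 0.47, and 912 changed by at least 1 on this scale, 303 up and 609 down. The libraries of the strains did not overlap for 36.8% of tested genes, against 10% by chance. Library size alone as the scaling gave 1945 higher and 2202 lower genes. Without the 2 C57BL/6 libraries that held Xist counts, which leaves 1 library in that strain, 1900 genes were called, and 1819 of these were among the 4000.

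**Figure D1:**
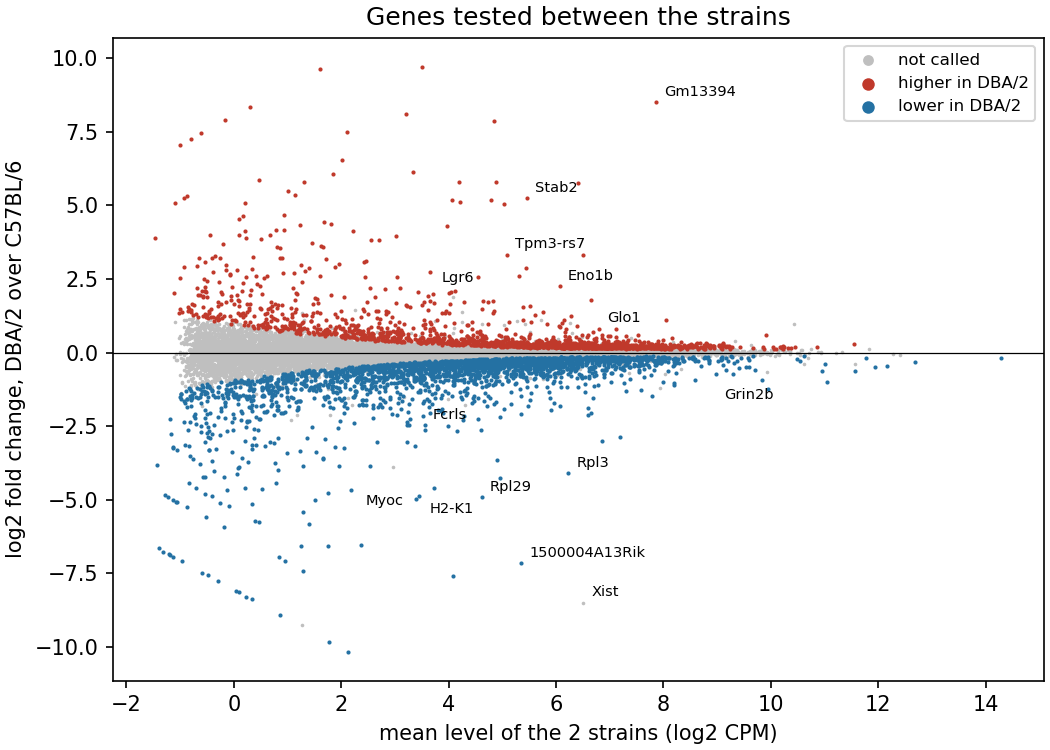
Log2 fold change of DBA/2 over C57BL/6 against the mean level of each of 17517 tested genes in log2 CPM, 1 point per gene, with called genes in red (1593 higher in DBA/2) and blue (2407 lower). Xist lies at the bottom without a call because its counts came from 2 of 3 C57BL/6 libraries.

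Some of the largest rises were in genes with little or no signal in C57BL/6. Sycp1, a protein of the meiotic synaptonemal complex (chromosome 3, 102818499 to 102936100), had 0 counts in C57BL/6 and 6.07 ± 0.74 CPM in DBA/2 (SD, n = 3), at least 103-fold higher against a floor of 3 counts over the C57BL/6 group. Stab2 (chromosome 10, 86841198 to 87008025) rose by a log2 fold change of 5.26 ± 0.31 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000374). Catsperg2, a subunit of the sperm calcium channel, rose 17.5-fold to 8.81 ± 2.18 CPM, and the flavin monooxygenase Fmo2 rose 6.10-fold to 5.21 ± 0.964 CPM (SD, n = 3). Lgr6, a receptor for R-spondins, rose from 5.3 ± 0.739 to 20.8 ± 2.12 CPM, and Tpm3-rs7, a tropomyosin-related sequence, from 6.06 ± 1.02 to 61.8 ± 3.11 CPM (SD, n = 3 each). Eno1b, Eif3j2 and Tagap, also among the largest rises, share sequence with another gene, and their direction turned when the counts of each family were summed. The summed log2 fold changes were -0.23 for Eno1b, -0.42 for Eif3j2 and -0.22 for Tagap. Catsperg2 also has a similar copy.

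Among the largest falls, Mndal, an interferon-inducible gene of the p200 family (chromosome 1, 173849126 to 173942491), had 8.70 ± 0.347 CPM in C57BL/6 (SD, n = 3) and 0 counts in DBA/2, at least 139-fold lower. Fam205c had 328 counts in C57BL/6 and 3 in DBA/2, a ratio of 104 with a 95% counting interval of 35.3 to 507. Myoc, the gene of the secreted protein myocilin, fell from 20.4 ± 4.29 to 0.625 ± 0.326 CPM, and Pttg1, the securin of sister chromatid separation, from 25.4 ± 1.61 to 1.02 ± 0.316 CPM (SD, n = 3 each). Zfp984, a zinc finger gene, fell from 5.21 ± 0.282 to 0.0917 ± 0.112 CPM, Mcmdc2 from 5.56 ± 0.582 to 0.170 ± 0.0497 CPM, and Fggy, a carbohydrate kinase, from 6.47 ± 1.3 to 0.233 ± 0.0558 CPM (SD, n = 3 each). The last of the 10 are H2-K1 and the ribosomal protein genes Rpl29 and Rps18, described with their groups. The uncharacterised transcript 1500004A13Rik fell from 80.6 ± 3.87 to 0.547 ± 0.303 CPM (SD, n = 3 each), with an adjusted p of 6.13e-21 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

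Genes known to carry sequence variants between these strains moved in both directions. Glo1, which encodes glyoxalase and is duplicated in DBA/2, rose from 80.8 ± 3.01 to 142 ± 5.3 CPM, and Alad, a heme synthesis enzyme that is also duplicated there, from 15.6 ± 0.83 to 41.8 ± 2.05 CPM (SD, n = 3 each). Gpnmb, which carries a nonsense allele in DBA/2J, fell by 2.90 on the log2 scale, and Kcnj9, a G protein-gated potassium channel, fell by 0.54. Gabra2, a GABA receptor subunit, had a log2 fold change of 0.17 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0136), which reached an adjusted p of 0.0752 without C57BL/6 replicate 3. Nnt, which carries a deletion in C57BL/6J, had 1.43 ± 0.148 CPM in C57BL/6 and 0.706 ± 0.213 CPM in DBA/2 (SD, n = 3 each), a direction opposite to its list, and its adjusted p was 0.128 without DBA/2 replicate 1. The complement gene Hc had 0.994 ± 0.406 and 0.586 ± 0.298 CPM (SD, n = 3 each) and was not called. Of variants below the count filter, H2-Ea-ps had 0 counts in C57BL/6 and 22 in DBA/2, at least 7.71-fold higher, and Ifi202b had 2 and 17 counts, a ratio of 8.94 (95% counting interval 2.12 to 79.8). Klrd1, listed as lower in DBA/2, had 1, 1 and 1 counts in C57BL/6 and 2, 2 and 3 in DBA/2, too few to show a direction.

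The antigen presentation list fell as a set, with 10 of 22 tested members lower in DBA/2 and none higher (12 lower adjusted over the list alone). Its median log2 fold change was -0.48 (camera, Benjamini-Hochberg adjusted p = 0.000129; adjusted p = 0.897 with an estimated correlation). The MHC haplotypes of the strains differ in sequence, so DBA/2 reads of H2 genes may map less well to the reference. How much of these falls is lost reads was not tested. H2-Aa, an MHC class II chain, had 59 counts in C57BL/6 and 2 in DBA/2, a ratio of 28.0 with a 95% counting interval of 7.43 to 237, and H2-DMb1, a class II loading factor with a similar copy, had 53 and 2 counts, a ratio of 25.2 (6.64 to 213). The interferon response list rose as a set, with 5 members higher and 1 lower of 27, and a median log2 fold change of 0.33 (camera, Benjamini-Hochberg adjusted p = 0.0343; adjusted p = 0.899 with an estimated correlation). That call was lost without any 1 of 4 of the 6 libraries, with an adjusted p up to 0.173 without DBA/2 replicate 1. Its largest called rises were Ifi27l2a, with 0.520 ± 0.177 and 1.13 ± 0.512 CPM, and Ifit3, which has a similar copy, with 3.21 ± 1.03 and 6.15 ± 2.17 CPM (SD, n = 3 each). Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment reached 0.24 for Ifi27l2a without DBA/2 replicate 1 and 0.141 for Ifit3 without C57BL/6 replicate 1. The 1 member called lower was Igtp, an interferon-induced GTPase, which had 3.63 ± 0.353 and 2.18 ± 0.307 CPM (SD, n = 3 each) and an adjusted p of 0.0741 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without C57BL/6 replicate 3.

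Microglia markers fell as a set, with 9 of 20 members lower and 1 higher and a median log2 fold change of -0.26 (camera, Benjamini-Hochberg adjusted p = 0.000797; adjusted p = 0.897 with an estimated correlation). Beside Fcrls, the complement chains C1qb and C1qc fell from 37.0 ± 1.52 to 14.4 ± 0.702 CPM and from 27.9 ± 1.78 to 11.3 ± 1.02 CPM (SD, n = 3 each). Immediate early genes fell with 12 of 22 members lower and none higher (16 lower and 1 higher adjusted over the list alone) and a median of -0.44 (camera, Benjamini-Hochberg adjusted p = 2.88e-05; adjusted p = 0.897 with an estimated correlation). Egr2 fell from 6.97 ± 0.713 to 2.77 ± 0.585 CPM and Ier2 from 9.03 ± 0.301 to 4.83 ± 0.446 CPM (SD, n = 3 each). Of 16 glucocorticoid response genes 6 fell, among them the growth regulator Ddit4 from 50.4 ± 5.62 to 36.6 ± 4.16 CPM (SD, n = 3 each), and the list did not pass as a set (adjusted p = 0.174). Of 16 clock genes 3 rose and 4 fell (adjusted p = 0.694), with Per3 up by 0.47 and Bhlhe40 down with a log2 fold change of -0.54.

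Markers of neighbouring thalamus and habenula were lower in DBA/2, with a median log2 fold change of -1.34 over 12 genes, 4 of them called (10 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 3.36e-05; adjusted p = 0.897 with an estimated correlation). Their mean log2 CPM per library was 4.69, 3.98 and 4.25 in C57BL/6 and 3.44, 2.58 and 2.41 in DBA/2. Zic1, a transcription factor of the medial habenula and thalamus, fell from 128 ± 15.8 to 69.5 ± 9.02 CPM (SD, n = 3 each). Moving with them, oligodendrocyte and myelin genes fell with 8 of 20 members lower and none higher and a median of -0.43 (camera, Benjamini-Hochberg adjusted p = 2.88e-05; adjusted p = 0.897 with an estimated correlation). Ppp1r14a, an inhibitor of protein phosphatase 1, fell from 16.0 ± 1.14 to 11.4 ± 2.15 CPM (SD, n = 3 each). Of 18 astrocyte markers 9 fell and 3 rose (camera adjusted p = 0.0557, which was 0.0267 without C57BL/6 replicate 3), with Ntsr2 down from 148 ± 3.76 to 88.5 ± 3.18 CPM and Gfap, the astrocytic intermediate filament, from 331 ± 36.1 to 213 ± 18.2 CPM (SD, n = 3 each). Of 9 oligodendrocyte precursor markers 4 fell, among them Olig1 with a log2 fold change of -0.27 (camera adjusted p = 0.542). Choroid plexus markers had a median of 0.51 with none of 15 called by edgeR (camera adjusted p = 0.0557, which was 0.000612 without C57BL/6 replicate 1, 0.000615 without DBA/2 replicate 3 and 0.325 without DBA/2 replicate 1), and Ttr, the transthyretin of that tissue, had 945 ± 396 and 1835 ± 700 CPM (SD, n = 3 each). Neocortex and striatum markers (2 of 11 higher, camera adjusted p = 0.536), vessel markers (2 higher and 1 lower of 19, adjusted p = 0.327), fibroblast and meninges markers (none of 12 called, adjusted p = 0.949) and red blood cell transcripts (none of 5 called, adjusted p = 0.445) did not pass.

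**Figure D2:**
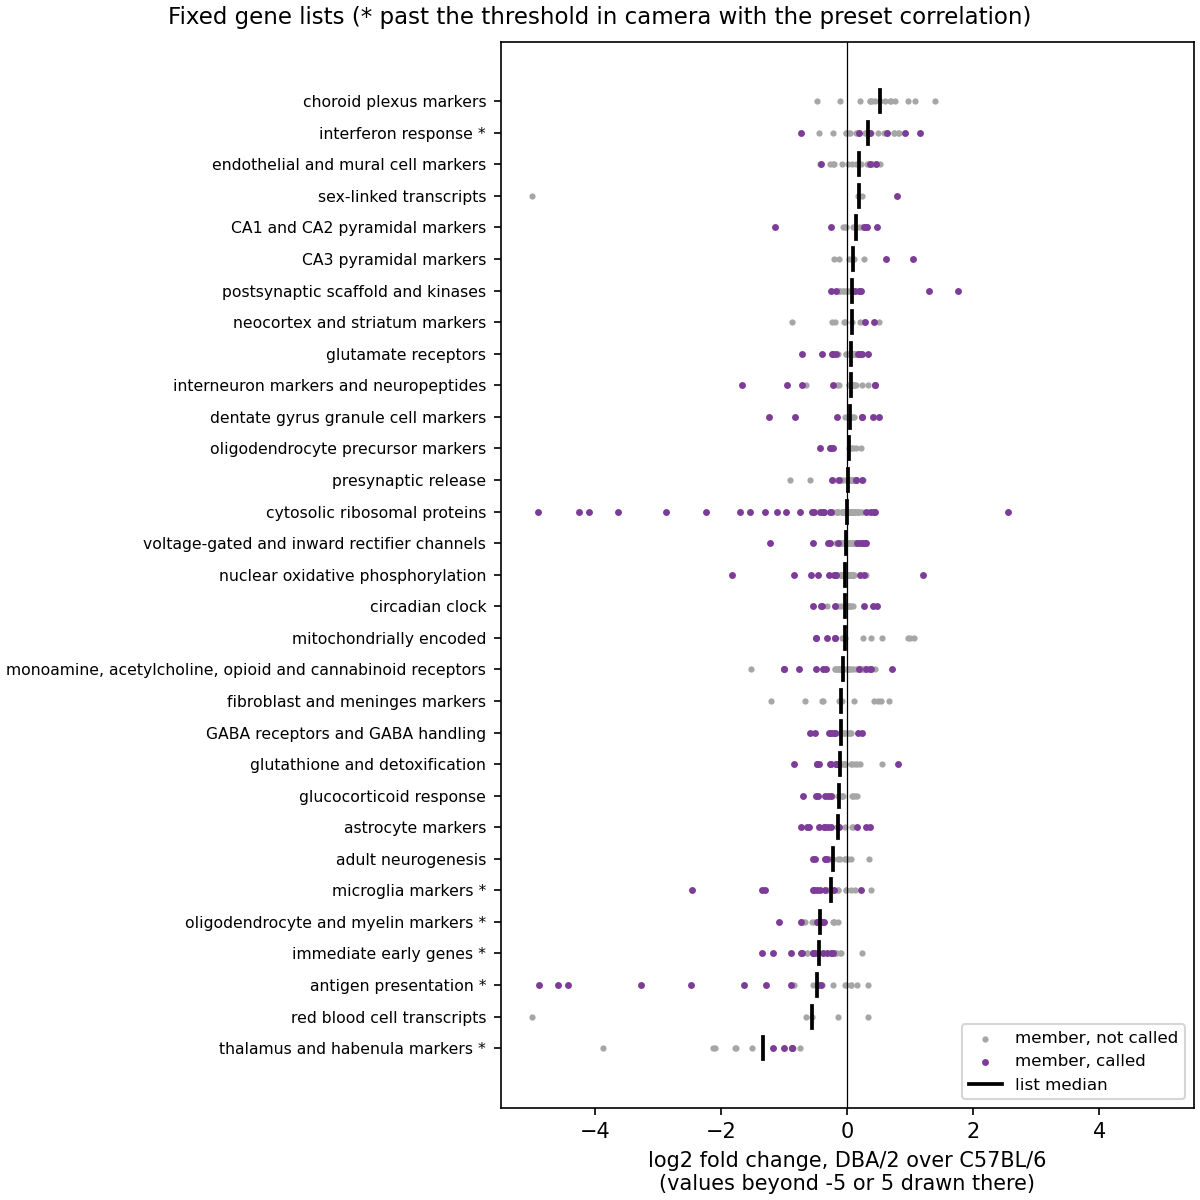
Log2 fold changes of DBA/2 over C57BL/6 for the members of 31 fixed gene lists, 1 point per gene, purple where called, with a bar at each list's median and a star where camera passed at its preset correlation. Thalamus and habenula markers have the lowest median, -1.34, and choroid plexus markers the highest, 0.51.

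Synaptic and channel genes changed in both directions, and none of these lists passed as a set in camera. Of 22 glutamate receptor genes 4 rose and 5 fell (camera adjusted p = 0.694): Grin2b, an NMDA receptor subunit, fell from 628 ± 51.0 to 382 ± 18.2 CPM, and Grin2a, another one, rose from 351 ± 12.6 to 440 ± 21 CPM (SD, n = 3 each). Grin2a has a similar copy, at 0.579 CPM in C57BL/6 and 0.863 CPM in DBA/2. The summed family had a log2 fold change of 0.331, against 0.326 for Grin2a alone. Of 26 postsynaptic scaffold and kinase genes 6 rose and 2 fell (camera adjusted p = 0.174; fry, higher in DBA/2, adjusted p = 0.032). Cacng8, an auxiliary subunit of AMPA receptors, rose from 4.18 ± 1.19 to 10.1 ± 3.12 CPM, and the scaffold gene Homer3 fell from 45.6 ± 0.425 to 37.9 ± 2.53 CPM (SD, n = 3 each). Of 21 GABA genes 2 rose and 6 fell (camera adjusted p = 0.11), with the transporter Slc6a11 down from 226 ± 23.6 to 150 ± 9.16 CPM and the receptor subunit Gabrb2 from 120 ± 6.06 to 84.2 ± 6.94 CPM (SD, n = 3 each). Of 24 presynaptic genes 3 rose and 2 fell (adjusted p = 0.73), and of 38 ion channel genes 6 rose and 5 fell (adjusted p = 0.949), among them the pacemaker channel Hcn4, down from 9.79 ± 1.78 to 4.22 ± 0.244 CPM (SD, n = 3 each). Of 38 modulatory transmitter receptors 5 rose and 6 fell (adjusted p = 0.694), with the kappa opioid receptor Oprk1 and the adrenergic receptor Adra1b both at -1.0 on the log2 scale. The thalamic markers named above were lower in the same DBA/2 libraries as these falls.

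Markers of hippocampal subfields moved in both directions. Of 12 CA1 and CA2 markers 4 rose and 2 fell (camera adjusted p = 0.513), of 9 CA3 markers 2 rose (adjusted p = 0.187), and of 14 dentate granule cell markers 4 rose and 3 fell (adjusted p = 0.694). Cdh24, a cadherin, rose from 30.0 ± 1.60 to 62.2 ± 6.21 CPM, and C1ql2, a secreted protein of mossy fibre synapses, fell from 56.5 ± 5.06 to 23.9 ± 2.47 CPM (SD, n = 3 each). Of 22 interneuron and neuropeptide genes 2 rose and 4 fell (adjusted p = 0.883), among them the peptide gene Cort from 2.59 ± 0.708 to 0.835 ± 0.289 CPM (SD, n = 3 each). Of 15 neurogenesis genes none rose and 4 fell (adjusted p = 0.0761), with the cyclin Ccnd2 down from 100.01 ± 2.33 to 78.7 ± 0.757 CPM (SD, n = 3 each).

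Ribosomal protein genes held some of the largest falls, and most of them have similar copies. Of 88 tested, 5 rose and 19 fell, the median log2 fold change was 0.00 and the mean -0.30 (camera adjusted p = 0.236). Rpl29 fell from 47.4 ± 5.21 to 1.58 ± 0.252 CPM, Rps18 from 58.9 ± 14.4 to 3.07 ± 0.701 CPM, and Rpl3 from 142 ± 2.16 to 8.23 ± 1.33 CPM (SD, n = 3 each). In 59 of these 88 genes reads could be split with a copy, so their levels are uncertain. With the counts of each family summed, the log2 fold change went from -4.91 to -1.51 for Rpl29 and from -4.09 to -0.18 for Rpl3. Rps18 went from -4.25 to -0.44 and was not called. The processed gene copies Gm13394, Gm15487 and Gm6969 had among the lowest adjusted p of all genes. Gm13394, which shares sequence with another gene so that its level is uncertain too, rose from 1.27 ± 0.109 to 463 ± 29.0 CPM (SD, n = 3 each). Gm15487 is the main copy of Atp6v0c and Gm6969 that of Cox7a2l, which are not ribosomal protein genes. The summed families of Gm15487 and Gm6969 had log2 fold changes of -0.10 and -0.23. Nuclear oxidative phosphorylation genes (3 higher and 8 lower of 75, camera adjusted p = 0.533) included Uqcrc1, a complex III core subunit, which rose from 4.61 ± 0.353 to 10.8 ± 2.94 CPM (SD, n = 3 each). Of 13 mitochondrially encoded genes 5 fell and none rose (camera adjusted p = 0.617), with mt-Nd5 down by a log2 fold change of -0.50. The mitochondrial share of all counts was 5.66% to 5.83% in C57BL/6 and 4.74% to 4.98% in DBA/2. Of 26 glutathione and detoxification genes 1 rose and 10 fell (adjusted p = 0.174), among them Gclm, a subunit of the glutathione synthesis enzyme, with a log2 fold change of -0.49.

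**Figure D3:**
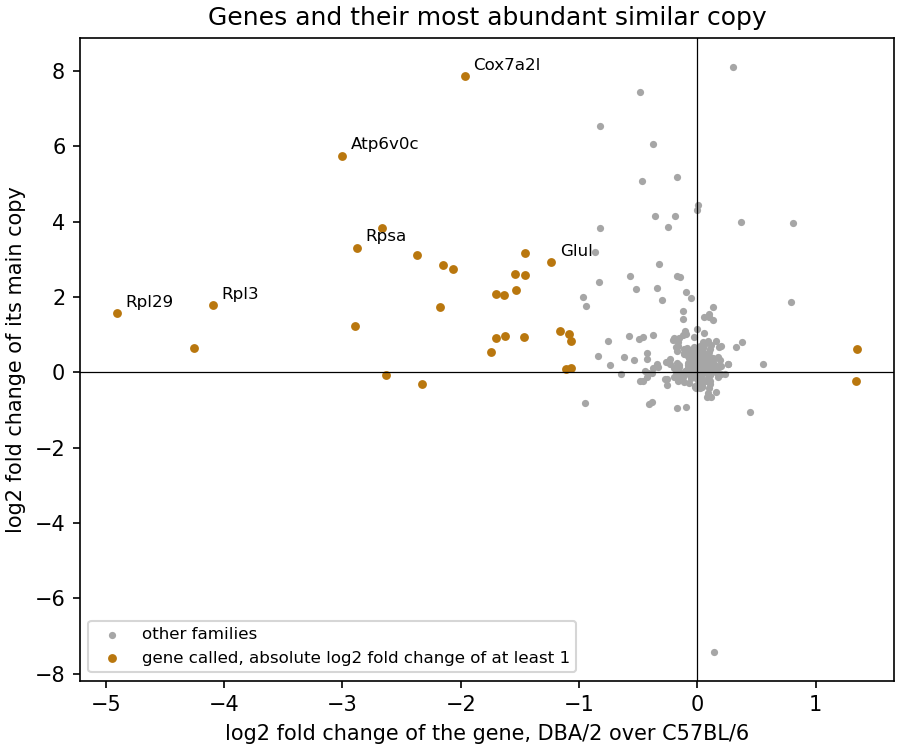
Log2 fold change of DBA/2 over C57BL/6 of 326 genes with introns, on the x axis, against that of their most abundant similar copy, on the y axis, 1 point per family. Of the 32 genes called with an absolute change of at least 1, in orange, 30 were lower in DBA/2.

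Beside the thalamus and habenula, antigen presentation and immediate early gene lists given above, the counts adjusted over the list alone differed for postsynaptic genes (6 higher and 4 lower adjusted over the list alone), GABA genes (2 and 10), ion channels (7 and 6) and neurogenesis genes (0 and 5). They also differed for astrocyte markers (3 and 10), myelin genes (0 and 13), vessel markers (1 and 1) and interferon response genes (6 and 1). The same held for clock genes (3 and 7), glutathione genes (1 and 11), ribosomal protein genes (5 and 20) and nuclear oxidative phosphorylation genes (3 and 6). The median and the mean or the direction of camera differed in sign for glutamate receptors, presynaptic genes, interneuron genes, dentate gyrus markers, oligodendrocyte precursor markers, ribosomal protein genes, mitochondrially encoded genes and sex-linked transcripts.

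Sex-linked transcripts differed within C57BL/6. Xist, the RNA of the inactive X chromosome in females, had 3214, 1 and 6995 counts in C57BL/6 replicates 1, 2 and 3 and 12, 10 and 2 counts in the DBA/2 libraries. The 4 Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were detected in all 6 libraries, and their summed level was 179 ± 33.3 CPM in C57BL/6 and 235 ± 18.2 CPM in DBA/2 (SD, n = 3 each). Xist was not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.114), and the sex-linked list did not pass as a set (camera adjusted p = 0.327). Of the Y-linked genes only Eif2s3y was called, with a log2 fold change of 0.80 and an adjusted p of 0.0165 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which became 0.0906 without DBA/2 replicate 2.

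**Figure D4:**
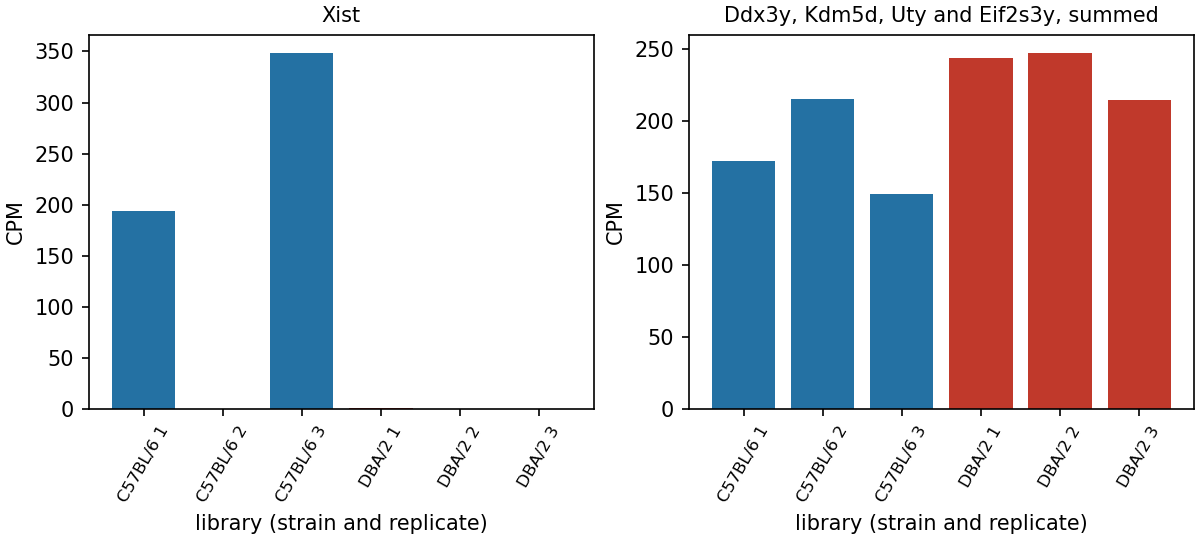
Level in CPM of Xist (left) and of 4 Y-linked genes summed (right), 1 bar per library, C57BL/6 in blue and DBA/2 in red. Xist reached 193 and 349 CPM in C57BL/6 replicates 1 and 3, which also had the lowest Y-linked sums, 172 and 150 CPM.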

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

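The fit on family sums and the fit without the 2 C57BL/6 libraries with Xist were chosen after seeing the data. The count of called genes was 4000 and stayed within 1.5 times of that, at 2865 to 4513, under every alternative chosen beforehand except the added fold threshold. With an absolute log2 fold change of at least 1 it was 912, with 303 higher and 609 lower, because the threshold is stricter. Limma on log2(FPKM + 1) called 1595 genes lower and on log2(FPKM + 0.1) 1569, against 2407, over 14707 tested genes; the cause was not tested. Without the 2 C57BL/6 libraries with Xist, 1900 genes were called, 624 higher and 1276 lower; only 1 C57BL/6 library was left, which is assumed to vary like the others. Leaving out each library in turn gave 3131 to 3717 genes. DESeq2 called 3252, of which 3179 were among the 4000. With the replicate number as a block, 3827 genes were called (1475 higher and 2352 lower), 3676 of them among the 4000. Correlations of same-numbered libraries over all tested genes were 0.132, -0.079 and 0.003, which showed no general pairing. They cannot exclude a shared order for some tissues. Choroid plexus, thalamus and habenula, and myelin markers each had their highest mean level in replicate 1 of both strains. Astrocyte and microglia markers did so too, by small margins. In DBA/2 replicates 1 and 2 the mean log2 CPM was 7.29 and 7.28 for astrocyte and 4.10 and 4.07 for microglia markers. Immediate early and antigen presentation genes did not. Summing families turned 5 named genes: Eno1b (-0.23), Eif3j2 (-0.42), Tagap (-0.22), Gm15487 (-0.10) and Gm6969 (-0.23), since the sums hold the reads of their parent genes.

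Of 102 named genes called, 82 were called in all 6 fits that leave out 1 library, and none turned direction. The other 20 lost the call in at least 1 such fit, among them Prkcd, Lef1, Mog, Pcp4, Mt2, Nes, Eomes, Cldn5, Ifit3 and Ifi27l2a. Of the 102, 29 lost the call without the 2 C57BL/6 libraries with Xist, Stab2 among them, 7 with DESeq2, 10 and 11 with FPKM (pseudocounts 1 and 0.1), 2 with limma-voom, 3 with the replicate block, 3 with family sums and 56 with the fold threshold. None lost it with the other scalings. The 5 lists called lower in DBA/2 passed in all 6 with camera's preset correlation, but none passed with an estimated correlation (adjusted p = 0.897 for each). With fry, microglia (0.00421), antigen presentation (0.00961) and immediate early genes (0.0249) passed, and thalamus and habenula (0.0607), myelin (0.12) and interferon response (0.314) did not. Lists that camera did not call but fry did were CA3 markers (0.00961, higher in DBA/2), postsynaptic genes (0.032, higher) and astrocyte markers (0.048, lower). Of the lists not called by camera, 6 passed without 1 of the libraries: choroid plexus, astrocyte, neurogenesis (0.033), GABA (0.0456), vessel (0.00965) and ribosomal protein genes (0.034). With the replicate block, choroid plexus (0.000267) and astrocyte markers (0.0493) passed. Median-ratio and quantile scaling of FPKM and limma without trend were not run, because counts were available.

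The real grouping gave 4000 called genes and the highest of the other splits of the 6 libraries gave 1. Each of the other splits mixed libraries of both strains within a group. The strain difference then adds to the spread within groups, so these low counts do not measure false calls. There are 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many. Depth limits the low genes, since 3 counts are 0.149 to 0.217 CPM.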

Other observations

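Gene Ontology terms enriched among the genes higher in DBA/2 were about learning and small GTPases. The hypergeometric test takes genes as independent. In camera the fixed lists of glutamate receptor, postsynaptic and presynaptic genes did not pass (adjusted p = 0.694, 0.174 and 0.73). Of 53 tested genes annotated to visual learning, 17 were higher against 4.6 expected (hypergeometric test, Benjamini-Hochberg adjusted p = 0.0013), and of 388 genes annotated to positive regulation of GTPase activity 63 were higher against 33.8 expected (adjusted p = 0.0013). Memory, regulation of synaptic plasticity and GTPase activator activity also passed, at adjusted p of 0.0374, 0.0374 and 0.0423, and these last 3 did not pass among genes without a similar copy. No term passed among the 2407 genes lower in DBA/2, where the lowest adjusted p was 0.607. Called genes were dense in parts of the genome: of 247 windows of 10 Mb, 21 were enriched and 8 depleted in called genes at an adjusted p under 0.05 (hypergeometric test), led by chromosome 2 from 120 to 130 Mb with 58 of 116 tested genes called (adjusted p = 3.09e-08) and chromosome 1 from 160 to 170 Mb with 40 of 73 (adjusted p = 3.73e-07). The latter window holds Myoc and Fmo2.

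In the weighing that follows, the 2 tests on Xist and Y-linked levels within C57BL/6 and the test on subfield markers were chosen after the results were seen. The others were written down before their own results, but those of the second pattern rest on family sums, which were added after seeing the data. A bound on a share counted as passed only where the 95% interval cleared it. That rule was made the same for all shares after the values were seen, and by its point value alone the family-sum test below would have met its bound.

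For the first pattern, the 4000 called genes, poorer mapping of DBA/2 reads to a C57BL/6 reference predicted over 60% lower genes. The share was 60.2% (95% interval 58.6 to 61.7), on the bound. It was 53.1% with library size as the scaling. Among the 912 called genes that changed by at least 1 on the log2 scale it was 66.8%. Poorer mapping therefore stays open. A difference in dissection was to be judged by the neighbouring-tissue lists' share of called genes, 0.15%, but that planned test was void, because these lists are too short to reach its bounds. Less thalamus in DBA/2 as the cause of the 303 rises of at least 2-fold needs hippocampal markers to rise alike. The median of 35 subfield markers was 0.084 (95% interval 0.017 to 0.231), which argues against it for those rises. That interval comes from resampled markers and does not measure the spread between libraries. For rises under 2-fold, and for myelin, astrocyte and receptor genes that fell, less thalamus stays open. A sex difference predicted a gap of over 10-fold that separates the strains, or under 2-fold if absent; the Y-linked ratio was 1.31 while Xist averaged 181 and 0.479 CPM without separating the strains, so neither bound was met. Local inherited differences predicted neighbouring calls. Both genes were called in 1056 adjacent pairs against 744.4 on average in random orders (permutation p = 1e-04, the smallest that 10000 orders can give). This met the prediction. The test cannot tell inherited differences in level from local differences in mapping, or from neighbours that change together with tissue. Tissue, age or origin of the animals remain untested.

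The second pattern is that genes with introns fell while similar copies rose in DBA/2: the main copy was called higher in 24 of 30 families whose gene fell by at least 1, and in 37 of 230 families whose gene was not called. If reads of 1 transcript were placed on the gene in C57BL/6 and on a copy in DBA/2, family sums were to change by less than 0.5 times the gene's change in over 50% of families; this held in 19 of 32, or 59.4%, with a 95% interval of 40.6 to 76.3 that includes 50, so this explanation stays open. Atp6v0c went from 205 to 25.6 CPM while Gm15487 went from 3.07 to 168 CPM, and their sum had a log2 fold change of -0.10. Lower ribosomal protein transcripts also stay open. The median of 48 family sums was 0.046, with a 95% interval of 0.006 to 0.075 from resampled families. This lay within the range set beforehand as counting against this cause. The median of the genes before summing, -0.024, already lay in that range, so this test could not tell. That limit was not part of the prediction. The mean went from -0.473 to -0.021 on summing. Of 12 families whose gene was called lower, 8 sums were still lower, Rpl29 at -1.51 and Rps2 at -0.81 among them. Of the 32 sums 27 were still called, 25 lower, as for Glul and Scoc, and 2 higher, Fau and Zfp983, so real changes or reads lost altogether stay open for those.

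The third pattern is Xist beside Y-linked transcripts in C57BL/6 replicates 1 and 3. Their Y-linked sums were 80.0% and 69.5% of that of C57BL/6 replicate 2, below all 4 libraries nearly without Xist, which is consistent with RNA from both sexes in these libraries. A whole library from a female mouse is argued against by the same values, since such a library would hold almost no Y-linked RNA. The labels' wording on the source of the RNA leaves open whether samples were pooled, and whether any mixing was by design or by accident was not tested.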
